A study of Caenorhabditis elegans with 6 samples.

How the data were processed

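Whole worms of 2 genotypes, wild-type N2 and atfs-1(et18), were synchronised by bleaching, raised on solid medium with E. coli OP50 and collected at L4, with 3 biological replicates per genotype, per the labels. Biotin-labelled cRNA was made from 2 ug of total RNA per sample and hybridised to Affymetrix C. elegans arrays, per the labels' protocols. The deposited intensity values are linear signals per probe set made with MAS5, per the submitters' processing notes; the version, the scaling target and the detection calls are not given in the sources used here. The deposited table holds 22625 probe sets on 6 arrays with no value at or below 0, and the equal mean after trimming 2% at each end (500.2 on each array) shows that each array had been scaled by 1 factor before deposit. MAS5 subtracts background and a mismatch signal, so ratios of dim probe sets are less certain than those of bright ones.

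From these signals log2 values were taken with no offset and no further scaling. The 77 control probe sets were left out, and of the other 22548 a probe set was tested if it lay above the 40th percentile of its own array on at least 3 of the 6 arrays, which left 13792. Gene names came from the platform annotation through its gene identifiers, updated with the gene table of assembly WBcel235 (20701 matched, 65 kept the annotation's symbol); 20766 probe sets had 1 symbol, 887 several and 895 none, and probe sets with several symbols were counted but never named. Each of 10613 genes was represented by its probe set with the highest mean log2 value. Of the 70 called genes with more than 1 tested probe set, 1 had a probe set of opposite sign. No coordinates are given because the sources name no genome build.

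Genotypes were compared as atfs-1(et18) minus wild-type with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, two-sided, Benjamini-Hochberg over the probe sets tested, adjusted p under 0.05), with counts at 2-fold or more beside. A gene not above the 40th percentile on any array of a genotype was given a bound, the other genotype's mean against the mean of that percentile, and its fold is written as at least that value. An exact test of 3 against 3 arrays cannot give a two-sided p under 0.1, so single values outside the model have no smaller p. The 30 gene lists, drawn up before the data were examined, were tested over genes with limma's camera at a preset inter-gene correlation of 0.01, Benjamini-Hochberg over the 29 lists with at least 3 tested members. Camera compares a list with the other genes; fry, run as a second description, asks whether a list's genes move one way on balance. Lists cover mitochondrial functions, detoxification, stress, immunity, metabolism, ribosome and proteasome, and the germline, stage and tissue make-up of whole worms.

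Genes to be named were chosen by a rule written before the data were examined: atfs-1; the 10 largest rises and 10 largest falls among called genes with 1 symbol, non-overlapping arrays and a mean above the median of tested genes; up to 4 called members of each list by size of change, or up to 2 with the smallest p where none was called; and hsp-6, hsp-60, gpd-2 and hmg-5. Exceptions are said to be so where they stand. Alternatives covered 2 other scalings, offsets of 16 and 64, no filter and a stricter one at the 60th percentile, 2 other variance priors, array weights, the replicate number as a block, probe sets that can bind several transcripts left out, the mean of a gene's probe sets, each array left out in turn, and 2 other set tests. A further 3 settings were chosen after seeing the data: the germline, stage and yolk genes left out, and 2 pairs of arrays left out. Counts and ranges over alternatives include these 3. On simulated arrays with the means and spreads of these 13792 probe sets and 200 of them changed, limma called 37.0% of 2-fold and 74.0% of 4-fold changes in the comparison of the genotypes, and 2.63% of its calls were unchanged probe sets. The simulated noise was independent between probe sets. On the real arrays 56.5% of the variation within genotypes lay on 1 shared axis, so these shares may not hold for the real comparison. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.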

Results

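RNA of whole Caenorhabditis elegans at the fourth larval stage (L4) was measured on Affymetrix whole-genome arrays in 2 genotypes, the wild-type strain N2 and atfs-1(et18), with 3 biological replicates each. ATFS-1 is the bZIP transcription factor of the mitochondrial unfolded protein response, and et18 is a point-mutation allele of its gene. The comparison asks which transcripts differ when ATFS-1 carries this mutation in worms grown on the bacterial food strain OP50. The signals had been scaled alike, with a trimmed mean of 500.2 on each of the 6 arrays and medians between 111 and 138. Across the probe sets tested, the correlation between arrays of 1 genotype lay between 0.937 and 0.973, and between genotypes it lay between 0.895 and 0.941. The number of arrays limits the precision of every value given.

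The transcript of atfs-1 itself (ZC376.7) was measured first. Its signals were 207, 284 and 277 in wild-type worms and 346, 355 and 289 in the mutant, so that each mutant array lay above each wild-type array, and the log2 change of 0.38 ± 0.20 (SE) did not pass the threshold (limma adjusted p = 0.400, range over its alternatives 0.267 to 0.657). Because et18 is a point mutation and not a deletion, this level is no check of the labels.

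In atfs-1(et18) worms, 286 genes were higher and 145 were lower than in wild-type worms. Among genes with a mean signal above the median of the genes tested, the largest rises were those of F15D4.5, the SWEET sugar transporter gene swt-6 and the claudin-like gene clc-11, and the 10 largest falls included those of the yolk protein genes vit-4 and vit-6 and the cathepsin B-like protease genes cpr-1 and cpr-4. The mitochondrial DnaJ gene dnj-10 and genes of mitochondrial protein import, mitochondrial thioredoxin and ubiquinone synthesis were among those that rose. The mitochondrial chaperone genes hsp-6 and hsp-60 were not called (limma adjusted p = 0.0773 and 0.663). All 5 yolk protein genes measured fell. Of 10613 genes tested, 301 passed the threshold with at least a 2-fold change, and at the level of probe sets 542 of 13792 passed it (limma, adjusted p under 0.05). The 3 arrays of each genotype did not overlap for all 431 genes called, and for 23.4% of all genes tested, where chance gives 10% on average. Genes vary together across the arrays, so the share over all genes can lie far from 10% without a genotype difference.

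F15D4.5 rose from a signal of 120 ± 18.1 (SD, n = 3) to 2799 ± 183, which is 23.5-fold (adjusted p = 1.94e-05). The rise of swt-6 was 19.7-fold (log2 change 4.30 ± 0.28 SE, adjusted p = 0.000160) and that of clc-11 was 12.8-fold (3.68 ± 0.36, adjusted p = 0.000926). For both genes 1 wild-type signal (61.3 and 66.7) lay below the 40th percentile of its array, so these folds are less certain, with log2 changes of 3.59 to 4.54 and 3.06 to 4.07 over their alternatives. The kinesin-associated protein gene kap-1 rose by 3.59 on the log2 scale, on a probe set marked as able to bind other transcripts. The cytochrome P450 gene cyp-33C8 rose 9.08-fold, the scramblase gene scrm-4 8.63-fold, T22B7.3 7.58-fold and cdr-2, of the cadmium-responsive family, 6.82-fold. The C-type lectin gene clec-4 rose 6.63-fold, and the long noncoding RNA tts-1 rose 5.94-fold with log2 signals of 7.59 ± 0.17 in wild-type and 10.16 ± 0.08 in mutant worms (SD).

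Among the falls, vit-4 dropped by 3.95 on the log2 scale (SE 0.40, adjusted p = 0.00117), from a signal of 2177 ± 840 to 146 ± 63.6. The signal of cpr-1 went from 15466 ± 1518 to 2309 ± 518 (log2 change -2.77 ± 0.19 SE, adjusted p = 0.000165) and that of cpr-4 from 16602 ± 3496 to 2532 ± 142 (-2.69 ± 0.17, adjusted p = 0.000156). Log2 changes of the other genes among these 10 falls, all with a mean signal above the median, were -2.77 for sdz-24, -2.62 for the ground-like gene grl-21, -2.42 for the C-type lectin gene clec-52, -2.19 for the collagen gene col-41, -2.18 for the yolk gene vit-6, -2.16 for scl-2 and -2.15 for cysl-2, of the cysteine synthase family.

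**Figure D1:**
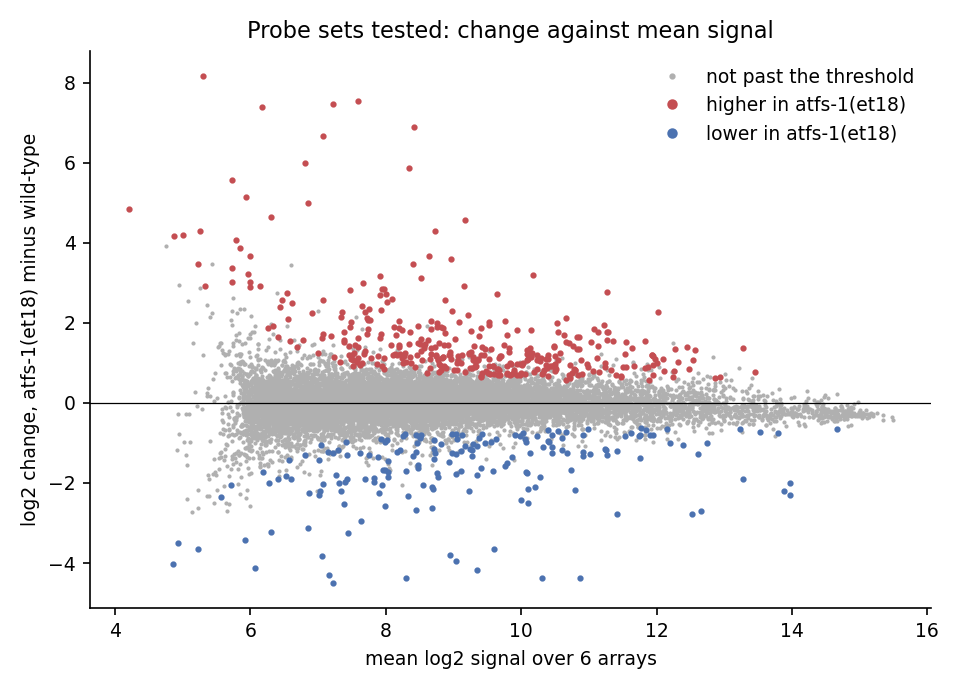
Log2 change of each probe set tested (vertical axis, atfs-1(et18) minus wild-type) against its mean log2 signal over the 6 arrays (horizontal axis), with probe sets past the threshold in red where higher and in blue where lower. The 542 coloured points include more rises than falls, and the rises reach higher than 4 on the log2 scale at dim and middle signals.

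**Figure D2:**
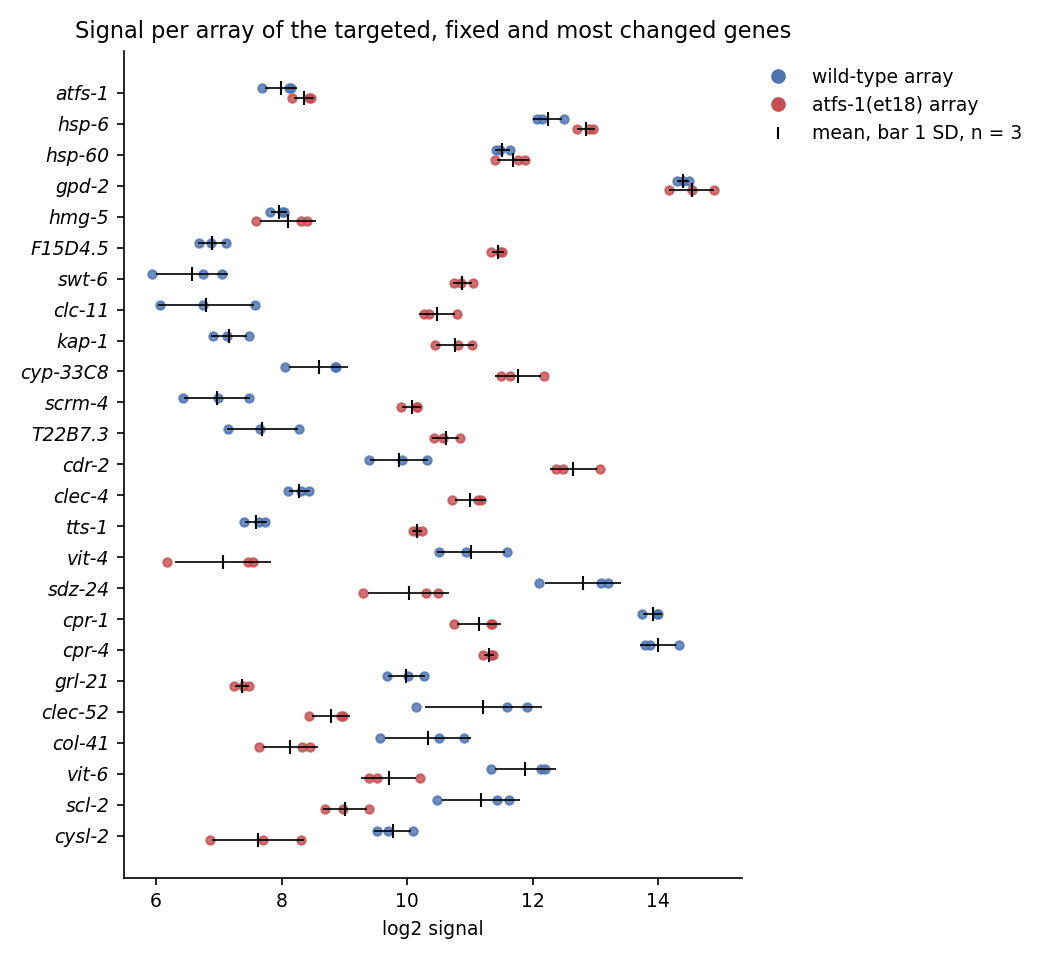
Log2 signal on each array for atfs-1, the 4 genes fixed in advance, and the 10 genes with the largest rise and the 10 with the largest fall among those with a mean signal above the median of the genes tested, with wild-type arrays in blue and atfs-1(et18) arrays in red, ticks at the mean and bars of 1 SD (n = 3). The genotypes are apart for these 20 genes by the rule that chose them. They are also apart for hsp-6 and, by a narrow gap, atfs-1, and overlap for hsp-60, gpd-2 and hmg-5.

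Mitochondrial chaperones, proteases and import components had the largest mean change of the mitochondrial lists. Of 18 members tested, 5 rose and 0 fell (11 and 0 adjusted over the list alone), and 17 had a positive change. Among them, dnj-10, which encodes a mitochondrial DnaJ protein, rose 2.14-fold (adjusted p = 0.00938), the import channel gene timm-23 rose by 0.90 ± 0.15 on the log2 scale (SE, adjusted p = 0.0120), the prohibitin gene phb-2 by 0.64 ± 0.14 and the import motor gene tin-44 by 0.61 ± 0.13. The calls of phb-2 and tin-44 ended in 10 of 20 alternatives each (highest adjusted p = 0.297 and 0.273), and that of timm-23 in 4 of 21. As a list they were higher by a mean of 0.43 (camera adjusted p = 7.01e-07). With an estimated correlation the adjusted p = 0.101, and over all alternatives it ran from 4.34e-09 to 0.101. The mitochondrial Hsp70 gene hsp-6 had a log2 change of 0.61 ± 0.16 with adjusted p = 0.0773, which fell under the threshold with quantile normalization, array weights or the mean of its probe sets (range over its alternatives 0.0129 to 0.304). The chaperonin gene hsp-60 had a change of 0.17 ± 0.16 (adjusted p = 0.663).

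For the mitochondrial ribosome, 2 of 57 genes rose and 0 fell (5 and 0 adjusted over the list alone), mrps-14 by 0.79 ± 0.13 and mrpl-2 by 0.77 ± 0.14 on the log2 scale, while 52 of the 57 had a positive change. The call of mrpl-2 ended in 8 of 21 alternatives (highest adjusted p = 0.143) and that of mrps-14 in 4 of 20. The list mean was 0.29 higher (camera adjusted p = 3.02e-08). Here the adjusted p = 0.265 with an estimated correlation (range over alternatives 1.52e-10 to 0.265). In the list of mitochondrial DNA maintenance and mitochondrial dynamics, 2 of 17 genes rose and 0 fell (3 and 0 adjusted over the list alone). Both belong to autophagy, lgg-2 (an LC3 homologue, 0.86 ± 0.14) and sqst-1 (the p62 homologue, 0.77 ± 0.15, on a probe set that can bind other transcripts). The sqst-1 call ended in 11 of 21 alternatives (highest adjusted p = 0.283) and the lgg-2 call in 5 of 21 (0.0722). That list was 0.34 higher on average (camera adjusted p = 0.000512), with adjusted p = 0.101 with an estimated correlation (range 2.98e-05 to 0.101). The gene of the mitochondrial DNA-binding protein hmg-5 had a change of 0.15 ± 0.25 (adjusted p = 0.824), which was -0.004 without atfs-1(et18) replicate 3.

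No gene of the tricarboxylic acid (TCA) cycle passed the limma threshold: 0 of 19, also 0 adjusted over the list alone and 0 at an unadjusted p under 0.05 (camera adjusted p = 0.386, fry adjusted p = 0.479). The members with the smallest p were idhb-1 (-0.43 ± 0.21) and sdha-1 (-0.28 ± 0.16). For the nuclear-encoded respiratory chain and ATP synthase, limma called 0 of 30 genes (0 adjusted over the list alone, 4 at an unadjusted p under 0.05), with asg-2 at -0.42 ± 0.15 and asb-1 at 0.54 ± 0.19. Its list mean of -0.07 turned to 0.04 with quantile normalization (camera adjusted p = 0.0759, fry adjusted p = 0.398), and the list passed the camera threshold without wild-type replicate 1 (adjusted p = 0.0247) or atfs-1(et18) replicate 2 (0.00674), with array weights (0.0355) and without probe sets that can bind several transcripts (0.0302). In glycolysis 1 of 16 genes rose and 0 fell (4 and 0 adjusted over the list alone), the aldolase gene aldo-1, 2.15-fold (adjusted p = 0.00748). The glycolysis list was 0.25 higher (camera adjusted p = 0.0123) with adjusted p = 0.494 with an estimated correlation (range 0.000704 to 0.494), and its adjusted p was 0.166 without wild-type replicate 1, 0.126 without atfs-1(et18) replicate 2, 0.116 with array weights and 0.133 without probe sets that can bind several transcripts. The glyceraldehyde-3-phosphate dehydrogenase gene gpd-2 had a change of 0.14 ± 0.18 (adjusted p = 0.777), and -0.04 without atfs-1(et18) replicate 2. No gene of the mitochondrial genome-encoded list was matched to a probe set of its own, so 0 were tested.

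Genes of xenobiotic metabolism moved both ways. Among cytochrome P450 genes 6 of 42 rose and 3 fell (9 and 5 adjusted over the list alone). Of the rising genes above the 40th percentile on some wild-type array, cyp-33C8 and cyp-14A1 had the largest changes. The rise of cyp-14A1 was 2.83 ± 0.22 on the log2 scale (SE, adjusted p = 0.000279). Of the wild-type signals of cyp-14A1, 60.8 and 59.6 lay below the 40th percentile of their arrays, so its fold is uncertain (log2 change 2.04 to 2.97 over its alternatives). The genes cyp-14A4 and cyp-13A8 were not above the 40th percentile on any wild-type array, and rose at least 3.18-fold and at least 2.73-fold against that level (adjusted p = 0.0104 and 0.0134). Of the UDP-glucuronosyltransferases, which conjugate lipophilic compounds, 8 of 46 rose and 3 fell (10 and 3 adjusted over the list alone). In this family ugt-19 rose by 2.21 ± 0.22 and ugt-44 by 1.83 ± 0.32, ugt-43 rose at least 1.75-fold, and ugt-53 fell at least 3.75-fold to below the 40th percentile on each mutant array. The ugt-43 call ended in 8 of 20 alternatives (highest adjusted p = 0.223). The camera test called neither list (adjusted p = 0.406 and 0.627). The median UDP-glucuronosyltransferase change was -0.12 while the mean, 0.14, and the test's direction were upward. The fry test placed the P450 list under the threshold (adjusted p = 0.0203), although its median change was 0.008, with 21 members higher and 21 lower.

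Of 28 glutathione S-transferases 1 rose and 1 fell (1 and 3 adjusted over the list alone), while 11 had a positive and 17 a negative change. The gene gst-29, with 1 wild-type signal below the 40th percentile (60.2), rose by 1.91 ± 0.31 (1.37 to 2.17 over its alternatives) and gst-20 fell by 1.07 on the log2 scale (SE 0.17) (camera adjusted p = 0.0759 for the list, 0.00976 without wild-type replicate 1, 0.0390 without atfs-1(et18) replicate 1 and 0.0378 with array weights). Of 20 antioxidant enzymes 2 rose and 0 fell (2 and 0 adjusted over the list alone). These were the mitochondrial thioredoxin gene trx-2, by 0.86 ± 0.13 (adjusted p = 0.00769), and the mitochondrial thioredoxin reductase gene trxr-2, by 1.46 ± 0.27 (adjusted p = 0.0202, a call that ended in 5 of 21 alternatives). The antioxidant list was not called (camera adjusted p = 0.147).

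Innate immunity genes changed in both directions, 10 of 109 rising and 11 falling (16 and 22 adjusted over the list alone). The lectin gene clec-17 rose 11.2-fold (log2 change 3.48 ± 0.25 SE, adjusted p = 0.000205), and clec-4 rose 6.63-fold. By contrast clec-52 fell 5.37-fold, a call that ended in 4 of 21 alternatives (highest adjusted p = 0.0826). The lysozyme gene lys-3 also rose, from wild-type signals of 28.4, 25.1 and 75.4, of which the first 2 lay below the 40th percentile of their arrays (80.7 and 68.5), so its fold is uncertain: the log2 change of 2.39 ± 0.50 (adjusted p = 0.0350) ran from 1.34 to 2.89 over 19 alternatives, of which 8 ended the call (highest adjusted p = 0.166, without atfs-1(et18) replicate 1). The list as a whole was not called (camera adjusted p = 0.389). Of 12 targets of the FOXO factor DAF-16, 3 rose and 0 fell (5 and 0 adjusted over the list alone). The gene dod-3 rose by 2.33 ± 0.22, the small heat shock protein gene sip-1 by 1.78 ± 0.22 and the ferritin gene ftn-1 by 1.19 ± 0.18. The DAF-16 list was 0.68 higher on average (camera adjusted p = 0.000226), with adjusted p = 0.101 with an estimated correlation (range 2.06e-06 to 0.101). In the cytosolic heat shock list 2 of 12 rose, sip-1 and hsp-17 (0.95 ± 0.15), and 0 fell (2 and 2 adjusted over the list alone), with a list mean of -0.12 that the test did not call (camera adjusted p = 0.215). For endoplasmic reticulum stress, limma called 0 of 20 genes (0 adjusted over the list alone, 6 at an unadjusted p under 0.05, camera adjusted p = 0.134, fry adjusted p = 0.0775), with pdi-2 at -0.42 ± 0.15 and pek-1 at 0.47 ± 0.18.

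Genes of the mevalonate pathway and of ubiquinone synthesis rose in 3 of 16 cases and fell in 0 (8 and 1 adjusted over the list alone). The ubiquinone synthesis genes coq-8 and coq-1 rose by 1.23 ± 0.15 (adjusted p = 0.00361) and 1.09 ± 0.16 (adjusted p = 0.00751), and fdps-1, encoding farnesyl pyrophosphate synthase, rose by 0.84 ± 0.16, a call that ended in 10 of 20 alternatives (highest adjusted p = 0.151). The list mean was 0.30 higher (camera adjusted p = 0.00563), and the adjusted p = 0.489 with an estimated correlation (range 0.000496 to 0.489). Without atfs-1(et18) replicate 2 its adjusted p was 0.0526. In lipid metabolism 3 of 65 genes rose and 4 fell (4 and 8 adjusted over the list alone; camera adjusted p = 0.135, and 0.0235 without wild-type replicate 1). The acyl-CoA dehydrogenase gene acdh-2 fell at least 9.35-fold, to below the 40th percentile on each mutant array, and its relative acdh-6 rose by 1.21 ± 0.15. The lipase gene lipl-1 fell at least 2.40-fold, and the stearoyl-CoA desaturase gene fat-7 dropped by 1.37 on the log2 scale (SE 0.29, adjusted p = 0.0345). The lipl-1 call ended in 8 of 20 alternatives and the fat-7 call in 7 of 21 (highest adjusted p = 0.137 and 0.145).

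**Figure D3:**
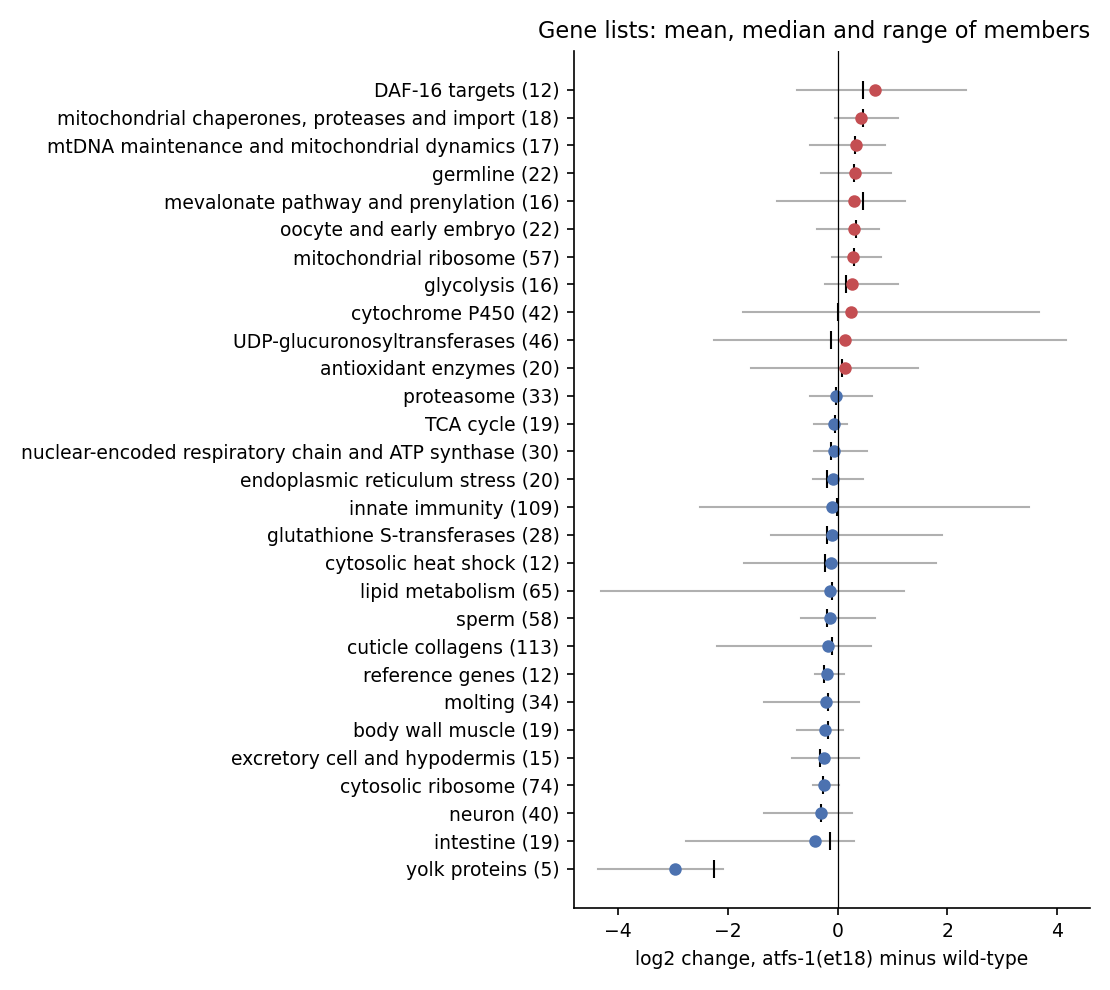
Log2 change (horizontal axis, atfs-1(et18) minus wild-type) of the 29 gene lists tested, each with the number of members tested in brackets, a point at the mean, a tick at the median and a line from the lowest to the highest member. The yolk proteins lie farthest from 0 with a mean of -2.97, and the UDP-glucuronosyltransferases have a mean and a median on opposite sides of 0.

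Yolk protein genes, which are expressed in the intestine and feed the growing oocytes, fell in 5 of 5 cases (5 adjusted over the list alone). Besides vit-4 and vit-6, vit-5 had a log2 change of -4.37 ± 0.48 (SE, adjusted p = 0.00189) and vit-2 of -2.25 ± 0.39 (adjusted p = 0.0152). The probe sets of vit-4, vit-5 and vit-6 are marked as able to bind related transcripts, and that of vit-2 is not. For vit-5 and vit-2, 1 mutant signal (31.8 and 66.9) lay below the 40th percentile of its array, and the log2 change ran from -4.84 to -3.43 and from -2.82 to -1.74 over the alternatives. The vit-2 call ended in 4 of 20 alternatives (highest adjusted p = 0.0900). The list mean was -2.97 (camera adjusted p = 1.34e-09), with adjusted p = 0.101 with an estimated correlation (range 9.88e-12 to 0.101). In the intestine list, 2 of 19 genes fell and 0 rose (2 and 0 adjusted over the list alone), the proteases cpr-1 and cpr-4. The intestine list's mean was -0.41 (camera adjusted p = 0.0119, adjusted p = 0.494 with an estimated correlation, range 4.93e-05 to 0.494). Its call ended with quantile normalization (adjusted p = 0.235) and without wild-type replicate 2 (0.0612), wild-type replicate 3 (0.207) or atfs-1(et18) replicate 3 (0.174).

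Germline lists had no member past the limma threshold, and none adjusted over the list alone. This was 0 of 22 germline genes, 0 of 22 oocyte and early embryo genes and 0 of 58 sperm genes, against 3, 5 and 11 at an unadjusted p under 0.05. The means of the germline and oocyte lists were 0.31 and 0.29 and that of the sperm list was -0.14. Their camera adjusted p values were 0.0247, 0.0252 and 0.0107, and each became adjusted p = 0.618 with an estimated correlation (ranges 3.12e-05 to 0.618, 0.000119 to 0.618 and 5.98e-06 to 0.793), while fry gave adjusted p = 0.456, 0.462 and 0.557. These lists varied within the genotypes: the germline mean was 0.37 above the mean of all arrays in wild-type replicate 1 and 0.39 above it in atfs-1(et18) replicate 3, and 0.51 below it in wild-type replicate 3. Germline examples are gld-3 (0.96 ± 0.31) and syp-3 (0.82 ± 0.31), oocyte examples puf-11 (0.75 ± 0.28) and mex-5 (0.55 ± 0.22), and sperm examples msp-65 (-0.45 ± 0.14) and msp-78 (-0.40 ± 0.13), the probe sets of mex-5 and both sperm genes being able to bind other transcripts. All 3 calls ended with quantile normalization (adjusted p = 0.0544, 0.0640 and 0.309). The germline call ended without wild-type replicate 2 (0.135), wild-type replicate 3 (0.366) or atfs-1(et18) replicate 3 (0.212), and the oocyte call without the same arrays (0.333, 0.152 and 0.196). The sperm list mean became 0.06 without wild-type replicate 1 (adjusted p = 0.566) and 0.02 without atfs-1(et18) replicate 2 (0.330), and its call ended with array weights (0.140). The stricter filter ended the germline call (0.101).

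Cuticle collagens fell in 3 of 113 cases and rose in 0 (2 and 0 adjusted over the list alone), col-41, col-39 (-1.67 ± 0.17) and col-146 (-0.74 ± 0.17, on a probe set that can bind other transcripts). Genes of the molting list fell in 3 of 34 cases and rose in 0 (3 and 0 adjusted over the list alone), the hedgehog-related genes wrt-8 (-1.34 ± 0.24), grd-10 (-1.24 ± 0.17) and wrt-4 (-0.83 ± 0.15). The calls of col-146, wrt-4 and wrt-8 ended in 9, 8 and 6 of 19 alternatives (highest adjusted p = 0.225, 0.105 and 0.0895). The list means were -0.17 and -0.22 (camera adjusted p = 0.00907 and 0.0107). With an estimated correlation the adjusted p = 0.592 and 0.494 (ranges 7.73e-06 to 0.592 and 0.00328 to 0.494). Without wild-type replicate 1 the adjusted p was 0.141 for the collagens and 0.0756 for the molting list, and with quantile normalization it was 0.191 for the collagens, as it was 0.173 without probe sets that can bind several transcripts.

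Markers of other tissues were called as lists but not as genes. In the body wall muscle list limma called 0 of 19 genes (1 adjusted over the list alone, unc-22 at -0.74 ± 0.17; 3 at an unadjusted p under 0.05, unc-54 among them at -0.38 ± 0.15). For neurons it called 0 of 40 (0 adjusted over the list alone, 4 unadjusted, with rab-3 at -0.51 ± 0.16 and ric-4 at -0.40 ± 0.14). For excretory cell and hypodermis it called 0 of 15 (0 adjusted over the list alone, 3 unadjusted, with aqp-8 at -0.83 ± 0.33 and elt-3 at -0.35 ± 0.14). The reference genes had 0 of 12 called (0 adjusted over the list alone, 2 unadjusted, cdc-42 at -0.36 ± 0.14 and act-3 at -0.33 ± 0.14). Means of these 4 lists were -0.23, -0.30, -0.24 and -0.19 (camera adjusted p = 0.00172, 0.00186, 0.0217 and 0.0193), and each list had adjusted p = 0.489 with an estimated correlation (ranges 0.000128 to 0.489, 0.000496 to 0.489, 0.0113 to 0.489 and 0.00737 to 0.489), with fry adjusted p = 0.0962, 0.214, 0.109 and 0.0982. Quantile normalization ended the calls of muscle (adjusted p = 0.295) and reference genes (0.333), and the reference call also ended without probe sets that can bind several transcripts (0.466). The neuron call ended without atfs-1(et18) replicate 2 (0.0714), the excretory and hypodermis call without that array (0.0714) or wild-type replicate 1 (0.0549) or with array weights (0.0546), and the reference call without wild-type replicate 2 (0.0912) or atfs-1(et18) replicate 3 (0.0764).

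Cytosolic ribosomal protein genes had a negative change in 73 of 74 cases, with no gene past the limma threshold (0 of 74, 0 adjusted over the list alone, 8 at an unadjusted p under 0.05). The list mean was -0.25 (camera adjusted p = 7.68e-11, adjusted p = 0.494 with an estimated correlation, range 3e-17 to 0.768, fry adjusted p = 0.195), with rpl-28 at -0.37 ± 0.13 and rpl-11.2 at -0.43 ± 0.16. Quantile normalization turned the mean to 0.01 (adjusted p = 0.768). The hybridisation controls, which are not worm RNA, were also lower on the mutant arrays, with a mean log2 difference of -0.29 ± 0.16 (SE) for the bright ones and -0.24 ± 0.15 for the less bright ones. Proteasome genes had 0 of 33 past the limma threshold (0 adjusted over the list alone, 1 at an unadjusted p under 0.05, camera adjusted p = 0.316, fry adjusted p = 0.394), with pas-7 at -0.51 ± 0.16 and rpn-6.2 at 0.62 ± 0.30. The proteasome mean of -0.03 turned positive without probe sets that can bind several transcripts.

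**Figure D4:**
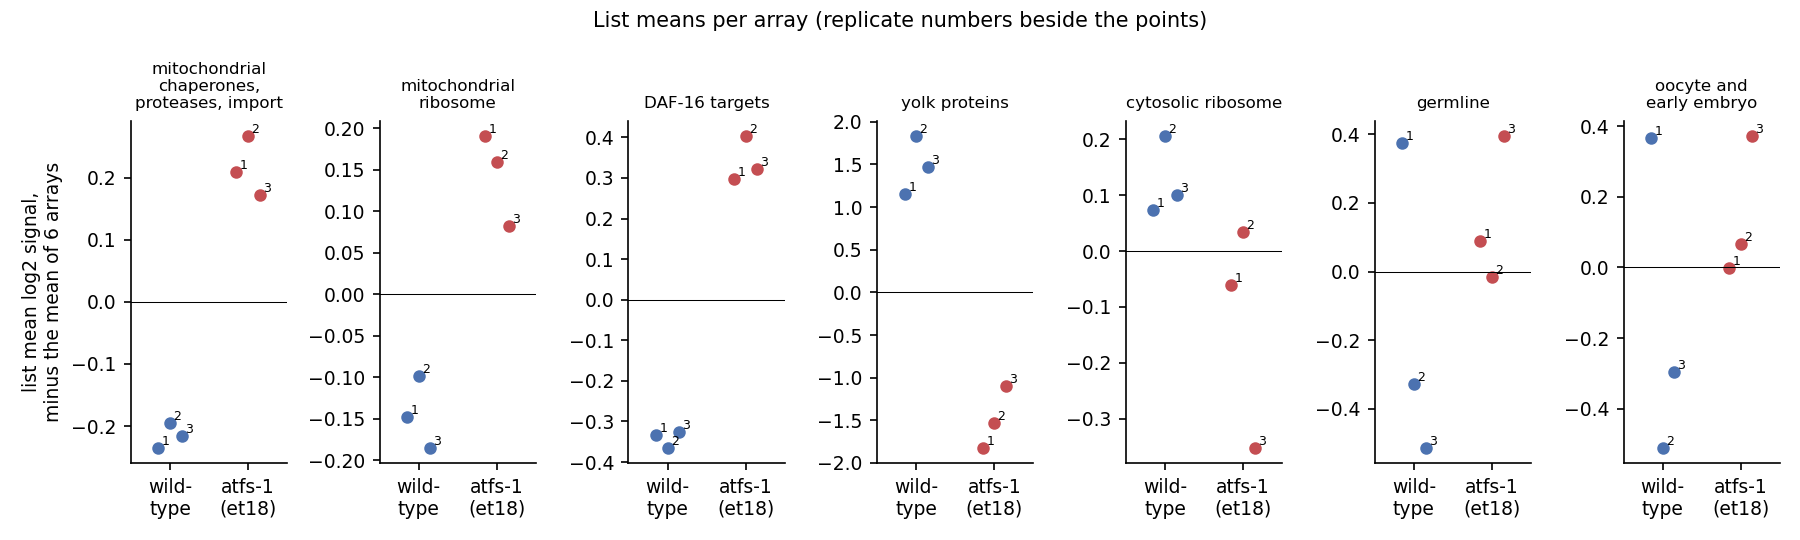
Mean log2 signal of 7 gene lists on each array (vertical axes, minus the mean over the 6 arrays, each panel on its own scale), with wild-type arrays in blue, atfs-1(et18) arrays in red and replicate numbers beside the points. The genotypes are apart for mitochondrial chaperones, mitochondrial ribosome, DAF-16 targets, yolk proteins and cytosolic ribosome, and overlap for germline and oocyte lists, where wild-type replicate 1 and atfs-1(et18) replicate 3 are highest or close to it.

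In all, 18 of the 29 lists tested passed the threshold of camera with its preset correlation of 0.01, 8 higher and 10 lower, while 0 did with an estimated correlation (5 at an unadjusted p under 0.05) and 7 did with fry, namely mitochondrial chaperones, mitochondrial ribosome, mitochondrial DNA maintenance and dynamics, cytochrome P450, DAF-16 targets, mevalonate pathway and yolk proteins. The number of genes called depended on single arrays: it was 698 without wild-type replicate 1, 181 without wild-type replicate 2, 292 without wild-type replicate 3, and 162, 244 and 223 without atfs-1(et18) replicates 1, 2 and 3. Of 60 named genes past the threshold, 31 passed it whichever array was left out, among them the 10 with the largest rise above the median signal, vit-4, vit-5, vit-6, cpr-1, cpr-4, sdz-24, grl-21, scl-2, dnj-10, coq-8, dod-3, sip-1, ftn-1, acdh-2 and acdh-6; calls lost without wild-type replicates 1, 2 and 3 numbered 1, 23 and 10, and without atfs-1(et18) replicates 1, 2 and 3 they numbered 28, 10 and 17.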

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

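Of the tests in this part, the one on genes near atfs-1 changed at least 4-fold was fixed before its result was seen; the tests on all called genes near atfs-1, the splits of the arrays, the ribosomal and yolk genes and the background were chosen afterwards. Worm genes also sit among the control probe sets, which the comparison left out, and in 5 of these 15 the 3 mutant arrays lay on one side of the 3 wild-type arrays (exact two-sided p = 0.1 each, the smallest possible). Several of the 15 measure the same gene at its 3' end, middle and 5' end, so they are not separate results. Among all genes tested, 23.4% had arrays that did not overlap. The 3 catalase control probe sets were higher in atfs-1(et18) worms by 0.89 (3' end), 0.85 (middle) and 0.81 (5' end) on the log2 scale, the 3' ubiquitin control was higher by 0.23, and the 3' actin control had a difference of -0.17. The 3' catalase difference rests in part on wild-type replicate 1, with log2 signals of 8.90, 9.82 and 10.26 in wild-type replicates 1, 2 and 3. The lowest mutant value there was 10.36. At the 5' end wild-type replicate 1 (log2 signal 5.20) lay below the 40th percentile of its array. Among the tested probe sets, the catalase gene ctl-2 had a change of 0.45 ± 0.24 (adjusted p = 0.379).

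For the number of calls, 1 of the 10 splits of the 6 arrays into 3 and 3 gave as many as the real one, which was the real split itself: it called 542 probe sets and the other splits at most 0. At an unadjusted p under 0.05 it gave 2373 probe sets, and the split of wild-type replicate 1 and atfs-1(et18) replicates 1 and 3 against the rest gave 2286. For gene lists the real split again stood alone as 1 of 10, but with 18 lists called against as many as 16 for another split, which set wild-type replicates 1 and 2 and atfs-1(et18) replicate 3 against the rest. With 10 splits no share under 0.05 can be reached. The second comparison shows that camera with a preset correlation calls many lists on splits that are not the genotypes. Those splits still divide the genotypes unevenly, so their calls can hold part of a genotype difference.

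Of the 89 genes with an estimated change of at least 4-fold, 15 were not above the 40th percentile on any wild-type array and 12 on any mutant array. A change of 4-fold is therefore not shown for each of them. After 64 was added to every signal, 87 (97.8%) stayed past the threshold and above 2-fold. The 40th percentile lay between 62.8 and 80.7, close to the added 64. A gene just above it in 1 genotype and near background in the other can therefore come close to 2-fold or pass it. The check cannot decide whether ratios of near-background signals are a source of the changes. By the same estimated folds, the 500 tested genes nearest to atfs-1 on its chromosome held 9 of these 89 genes against 80 of the other 10112 genes, an odds ratio of 2.298 (95% interval 1.01 to 4.62, Fisher's exact p = 0.0373). Sequence variants linked to the mutation may account for part of these changes. All called genes were over-represented there too (38 of 500 against 393 of 10112, odds ratio 2.03, 95% interval 1.40 to 2.88, Fisher's exact p = 0.000173), a count that does not rest on folds. The share with an estimated change of at least 4-fold was 1.8% among these 500 genes, 1.14% on the rest of the chromosome and 0.731% on the other chromosomes. Both tests set the neighbours against all other genes, so they cannot tell linkage apart from a difference of the whole chromosome. Genes of 1 family often lie side by side and are not independent, and how many of the changes come from linkage was not measured. The effect of the atfs-1 mutation itself stays open and was not separated from the strain background.

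The fall of yolk protein genes (list mean -2.97, 95% interval -3.76 to -2.17) could come from probes shared between near-identical genes, but vit-6, the most distant in sequence, fell by 2.18 (SE 0.28) as well, and so did vit-2, whose probe set is not marked as shared (-2.25, SE 0.39). These values argue against shared probes as the whole source, although the vit-6 probe set is itself of a kind that can bind related transcripts. The test for stage assumed that younger mutant worms at harvest would have lower oocyte genes too, which was not checked. The oocyte and early embryo list had a change of 0.29 with a 95% interval of -0.51 to 1.09, too wide to decide, so stage and genotype cannot be told apart for the yolk genes. The genotype remains an open, untested explanation.

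The lower signal of cytosolic ribosomal protein genes may have a technical source. The genes of the highest of 10 signal classes had a median change of -0.12, and after quantile normalization it was -0.01. Quantile normalization gives all arrays the same distribution, so the smaller second value follows largely from the method. A real fall of the brightest genes would be removed in the same way, so this step cannot separate a technical source from a biological one. The bright hybridisation controls had a change of -0.29, as large as the list change of -0.25, but with a 95% interval of -0.73 to 0.15 that leaves a difference in signal range open (the rule for reading them was made stricter, from 1 SE to this interval, after their values were seen). The less bright controls (bioB and bioC), pooled in the same way, had a change of -0.24 (SE 0.15), so the pooled values show no clear difference between the brighter and less bright controls. These controls are not dim: the 3' bioB probe set averaged 625 in wild-type and 547 in mutant arrays, against median signals of 122 and 121. The comparison therefore does not cover low signals. For the 3' probe set of each control alone, the difference of the mean log2 signals was -0.18 for bioB, -0.16 for bioC, -0.24 for bioD and -0.46 for cre. That of cre, the brightest, was lower on each mutant array than on each wild-type array. Without atfs-1(et18) replicate 3, the lowest array, the list's change was -0.14 (95% interval -0.34 to 0.06), so a single array cannot be told apart from a difference of both groups, and a difference between genotypes in the mRNA levels of these genes stays open.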

How the results depend on the processing

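All settings here were planned except 3 chosen after seeing the data: leaving out the germline, stage and yolk genes, and leaving out 2 pairs of arrays that lie at the ends of the main variation within genotypes. Of the genes called in the main comparison, 378 of 431 were also called with quantile normalization, 334 with median centring, 430 and 429 with offsets of 16 and 64, 376 with no filter, 393 with the stricter filter and 427 with robust eBayes, each in the same direction. Without the stage genes 420 were shared, and without wild-type replicate 1 and atfs-1(et18) replicate 3 together 323. The prior without a trend shared 268 and the replicate block 258, and leaving out 1 array shared from 159 (atfs-1(et18) replicate 1) to 399 (wild-type replicate 1). Array weights moved the counts to 1637 probe sets, 1298 genes and 535 genes at 2-fold or more. The prior without a trend left 285 genes. Leaving out probe sets that can bind several transcripts left 313 probe sets; fewer were tested, and named genes with no other probe set, atfs-1 among them, have no value there. The mean of a gene's probe sets gives no probe-set count, and lists left out with the stage genes have no value in that setting. Without wild-type replicate 3 and atfs-1(et18) replicate 2 together there were 255 probe sets, 195 genes and 195 at 2-fold or more. For each other change the cause was not tested.

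The signals gave no clear sign that the replicate numbers pair the arrays. Same-numbered arrays had correlations of their deviations of 0.17, 0.18 and -0.40, and 2 of 6 arrays matched their own number best. With 3 arrays per genotype these values cannot exclude pairing. The 3' to 5' signal ratio of the Gapdh control was 1.75 in wild-type and 1.74 in atfs-1(et18) replicate 1. It was 1.44 in both replicates 2, but 1.81 in wild-type and 1.48 in atfs-1(et18) replicate 3. The actin ratios, too, were closer for replicates 1 and 2 than for replicate 3. Whether same-numbered samples were handled together was not tested. The fit with the replicate block called 336 probe sets and 267 genes, with fewer residual degrees of freedom.

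Leaving out 1 array in turn gave 202 to 871 probe sets, 162 to 698 genes, 160 to 423 genes at 2-fold or more and 14 to 19 gene lists, and the share of called genes that were higher ran from 63.5% to 75.1%. Gene lists past the threshold numbered 10 with quantile normalization, 0 with camera's estimated correlation and 7 with fry. Some list means changed sign: with quantile normalization the respiratory chain (0.0415) and the cytosolic ribosome (0.0115); with no filter the glutathione S-transferases (0.0823); with the stricter filter innate immunity (0.00273) and cytosolic heat shock (0.0791); without probe sets that can bind several transcripts the proteasome (0.0302) and sperm (0.0457); and without wild-type replicate 1 and atfs-1(et18) replicate 3 together the proteasome (0.0104). Leaving out 1 array turned the sperm list (-0.311 to 0.0587), gpd-2 (-0.0417 to 0.315) and hmg-5 (-0.00439 to 0.403). Signals under the 40th percentile limit what dim genes can show, since no detection calls were used.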

Other observations

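The tests in this part were chosen after the data were seen. Transthyretin-like genes, a large nematode family of secreted proteins, were over-represented among the genes that fell in atfs-1(et18) worms: 5 of 34 tested fell, with log2 changes of -1.06 for ttr-15, -1.19 for ttr-31, -1.29 for ttr-32 and -1.97 for ttr-8 and a fall of at least 2.94-fold for ttr-1, 1 rose and the others did not pass the threshold (Fisher's exact test, Benjamini-Hochberg adjusted p = 0.0172). When all 288 families of 5 or more tested genes with a shared symbol were tested for rises and for falls, 3 of 576 tests passed, the others being yolk proteins (adjusted p = 2.56e-07) and rising UDP-glucuronosyltransferases (adjusted p = 0.00778). Neighbouring copies within a family are not independent, and related transcripts can share probes.

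Some large changes lie among genes of no list that are too dim in 1 genotype to be named by the rule. Those with the largest bounds are named here, rises before falls and each in the order of their bounds, after their values were seen. Genes with smaller bounds in their direction were left out, such as F22B3.7, which rose at least 5.57-fold. C38D9.2 rose at least 36.7-fold, C07G1.7 at least 27.8-fold, F41G4.7 at least 19.1-fold and F40D4.13 at least 13.2-fold from signals below the 40th percentile on each wild-type array, and pud-3 and C09B8.4 fell at least 10.4-fold and at least 4.16-fold to below that level on each mutant array. The probe sets of F41G4.7 and C09B8.4 are marked as able to bind other transcripts. No function is assigned to these genes here.

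Within the genotypes, 56.5% of the variation between replicate arrays lay on 1 axis, with wild-type replicate 1 (0.58) and atfs-1(et18) replicate 3 (0.39) at one end and atfs-1(et18) replicate 2 (-0.53) and wild-type replicate 3 (-0.41) at the other. Germline genes followed it: the median loading of the germline list was above that of 100% of 10000 random lists of the same size and mean signal, as were the medians of the sperm, oocyte and cuticle collagen lists. Other lists lay at the opposite end, intestine and innate immunity below all random lists (percentile 0), lipid metabolism at percentile 0.12, UDP-glucuronosyltransferases at 0.31 and glutathione S-transferases at 0.37. The axis is therefore not one of germline genes alone. Random lists hold unrelated genes, while members of a list can vary together (estimated correlation 0.648 for the germline list). Such lists reach extreme percentiles more easily, so the percentile does not measure a link to germline development. The replicate cultures may have differed in germline development at harvest, or in another trait that moves these lists together, a hypothesis found and tested on the same arrays.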
